A study of Mus musculus with 2 samples.

How the data were processed

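Small RNA libraries were made from total RNA of the gastrocnemius of male B6CASTF1/J mice aged 36 days, with a size range under 30 per the labels, and sequenced as microRNA-seq. The labels give 1 tissue, 2 biological replicates with 1 technical replicate each, and descriptions naming 2 different males. They also give both the same donor identifier, which is read here as a label of the strain. Both libraries were placed in 1 group, and no sample was left out.

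The authors deposited 1 table per library, with whole-number read counts for each of 2202 microRNA genes. Per the labels and the deposited file descriptions, the assembly was mm10 and the annotation GENCODE M21. The aligner, the counting program and the adapter trimming are not given in the sources used here. Each table has 3 count columns, which ignore strand, count reads on the gene's strand, and count reads on the opposite strand. It also has 4 rows that name no gene, for reads that were unmapped, aligned to several loci, outside any gene, or ambiguous between genes. This layout is the one in which reads aligned to several loci are added to no gene, and the deposited counts are taken to follow it. No normalization had been applied to the deposited counts, as their totals differ between libraries.

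The rows that name no gene stayed out of the library sizes. Of 19726010 reads in replicate 1, 70.4% aligned to several loci, 7.05% were unmapped, 1.63% fell outside any microRNA gene and 20.96% were counted. Of 16764463 reads in replicate 2, the shares were 73.3%, 6.02%, 1.51% and 19.2%. If such reads are in no gene's count, as the layout implies, microRNAs encoded more than once can be undercounted. CAST alleles that differ from mm10 can also lower a count, which is not analysed here. The same-strand column was the main measurement, by a rule to take the strand column with most counted reads. In the column that ignores strand, 988119 reads of replicate 1 and 833648 of replicate 2 were ambiguous, because 64 of the genes overlap a microRNA on the opposite strand. Mir378a, Mir126a and Mir338 are among these, and their count is at or near 0 in that column.

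Gene symbols, positions and host genes came from the GENCODE M21 annotation, in which all 2202 identifiers were found, and 1 symbol was shared by 2 identifiers. Hairpin sequences came from its transcripts. Alternative symbols were resolved through a RefSeq gene table used for names alone. Mir486b was matched as Mir3107, Mir142a as Mir142, Mir146a as Mir146, and Mir7a-1 and Mir7a-2 as Mir7-1 and Mir7-2. The list member Mir696 had no match and is not analysed here.

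Abundance was expressed as CPM of the counts on the gene's strand, with mean and SD over 2 libraries. Exact Clopper-Pearson 95% intervals were computed for shares in single libraries, and a count of 0 was taken to allow up to 3 counts. Intervals cover counting error only, since PCR copies are not independent molecules. Ratios between 14 fixed pairs of genes were log2 ratios of counts + 0.5. The log2 ratio between libraries was replicate 2 over replicate 1 of CPM + 1, scaled by TMM (factors 1.06 and 0.944), for genes with a mean of at least 10 CPM. The pseudocount makes ratios of low genes smaller. With 1 group there was no test between conditions, and edgeR was used for TMM factors and for the common dispersion of an intercept-only model over genes with at least 10 summed counts. A chi-square test of homogeneity compared the libraries' counts over the same genes. The median ratio of each list was placed among 10000 random lists of equal size matched on mean expression. All of this describes 2 animals, and their spread cannot be divided into biological and technical parts.

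Choices fixed before the data were examined were the tests of the composition and of the replicate comparison, the pairs, 23 lists and the rule for naming genes. Genes were named if they were among the 20 highest in mean CPM, were members of a fixed pair, were among the 5 largest ratios in each direction, or were among the 4 highest of a list (all members for striated muscle). Genes outside this rule are marked as such. Lists covered striated muscle, myosin-intron, denervation and regeneration, and metabolic muscle microRNAs. They also covered let-7, miR-30, miR-29, miR-26, miR-10 with miR-100, miR-23 with miR-27 and miR-24, the Mir17hg cluster, miR-106b-25, miR-106a-363, Dlk1-Dio3 and other imprinted microRNAs. Cell types were red cells, leukocytes, endothelium, smooth muscle with fibroblasts, neurons with glia, liver, epithelium with skin, and endocrine cells. Endothelium and liver are 1 gene each, and Mir206 and Mir23a stand in 2 lists. The myosin-intron list (Mir208a, Mir208b and Mir499) lies wholly within the striated muscle list.

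Alternatives were the column ignoring strand, total-count scaling, TMM, DESeq2 size factors, library sizes without the most abundant gene or with all reads, other minimums and pseudocounts, other dispersion estimates, single-copy genes, equal depth, and leaving out each replicate. The procedures were tested on simulated data. With counting noise alone, the chi-square test gave p = 0.357, and a simulated coefficient of variation of 0.1 was recovered as 0.101. Among 2202 simulated genes, 200 were changed 4-fold between replicates, 108 of them above the minimum, and all 108 were recovered in the right direction, with 0 of 150 unchanged genes called. These genes were simulated with a coefficient of variation of 0.1, below the 21.4% estimated for the 2 libraries. The 0 therefore gives no rate of false calls at the real spread. A list of 30 genes shifted by −0.4 log2 units was placed at percentile 0, and the same list unshifted at 90.5. Its genes were simulated independently with the same coefficient of 0.1, so this gives no error rate for the percentiles of the real lists.

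Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.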

Results

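MicroRNAs were profiled in the gastrocnemius, the large calf muscle, of male B6CASTF1/J mice aged 36 days. These mice are first-generation hybrids of C57BL/6J and the wild-derived CAST strain. The 2 libraries, replicates 1 and 2, form 1 group, and their labels describe 2 different male animals. Replicate 1 held 4134880 reads counted on the strand of an annotated microRNA gene and replicate 2 held 3219740. Those counted reads made up 20.96% of all reads in replicate 1 and 19.2% in replicate 2. Because the series has no second condition, the comparisons are among microRNA genes within the muscle and between the 2 animals. Abundance is given as CPM, a gene's count per 1000000 counted reads of its library, as mean ± SD with n = 2, and positions refer to mm10 with the GENCODE M21 annotation.

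The first question was which microRNA genes held the counted reads of this muscle. Mir378a, which lies in an intron of the metabolic regulator Ppargc1b, held the most at 130385 ± 10039 CPM (n = 2). Mir22, a microRNA of heart and skeletal muscle, followed at 119561 ± 13609 CPM. Mir126a, carried by the endothelial gene Egfl7, reached 90623 ± 7368 CPM, and Mir143, typical of smooth muscle, reached 86966 ± 5761 CPM. Mir378a exceeded Mir22 by 0.13 ± 0.05 on the log2 scale (SD, n = 2), in both libraries. This ranking covers reads counted in single genes, while 71.8% of all reads on average aligned to several loci. In replicate 1, 3.67% of the reads aligned to several loci would equal the count of Mir378a, so a microRNA encoded at several loci, such as Mir1a, is not ranked by it.

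Mir378a (ENSMUSG00000105200.1) maps to the minus strand of chromosome 18, from 61397835 to 61397900. Mir22 (ENSMUSG00000065529.1) lies on the plus strand of chromosome 11, from 75463716 to 75463810, within exons of its host transcript Mir22hg and of Tlcd2. Mir126a (ENSMUSG00000065540.1) occupies chromosome 2 from 26591357 to 26591429 on the plus strand, where the annotation places an exon of Egfl7. Mir143 (ENSMUSG00000065445.3) is on the minus strand of chromosome 18 from 61649196 to 61649258, with no host gene on its strand.

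Below these 4 genes, Mirlet7g reached 49724 ± 1188 CPM and Mirlet7i 41638 ± 2970.2 CPM. The pair Mir23b and Mir23a stood at 41438 ± 4161 and 32620.4 ± 3687 CPM. Mir21a, a microRNA of growth and injury responses that lies in an untranslated exon of Vmp1, reached 33610.1 ± 228 CPM. Mir206, the skeletal muscle microRNA, ranked in place 10 at 27262 ± 2019 CPM. Mir99a, Mir30a, Mir26b, Mirlet7d, Mirlet7b, Mir322, Mir30d, Mir10b, Mir411 and Mir127 completed the leading 20, from 23715 ± 2840.1 CPM for Mir99a down to 11134 ± 1418 CPM for Mir127.

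A few genes held most of the counted reads. Mir378a alone took 13.0% ± 1.00, the leading 5 genes took 47.7% ± 3.56, and the leading 10 took 65.4% ± 2.70. The leading 20 took 82.0% ± 1.64, and these were the same 20 genes in both libraries. Of 2202 microRNA genes in the tables, 295 had at least 10 counts in both libraries, 324 in replicate 1 and 301 in replicate 2. A further 1563 genes had no counted read in either. For reads aligned to 1 locus, a count of 0 allows up to 0.726 CPM in replicate 1 and 0.932 CPM in replicate 2. It sets no limit on reads aligned to several loci, and 968 of the 1562 such genes with a sequence share at least 20 bases with another hairpin. These limits, like all intervals given here, cover counting error only.

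**Figure D1:**
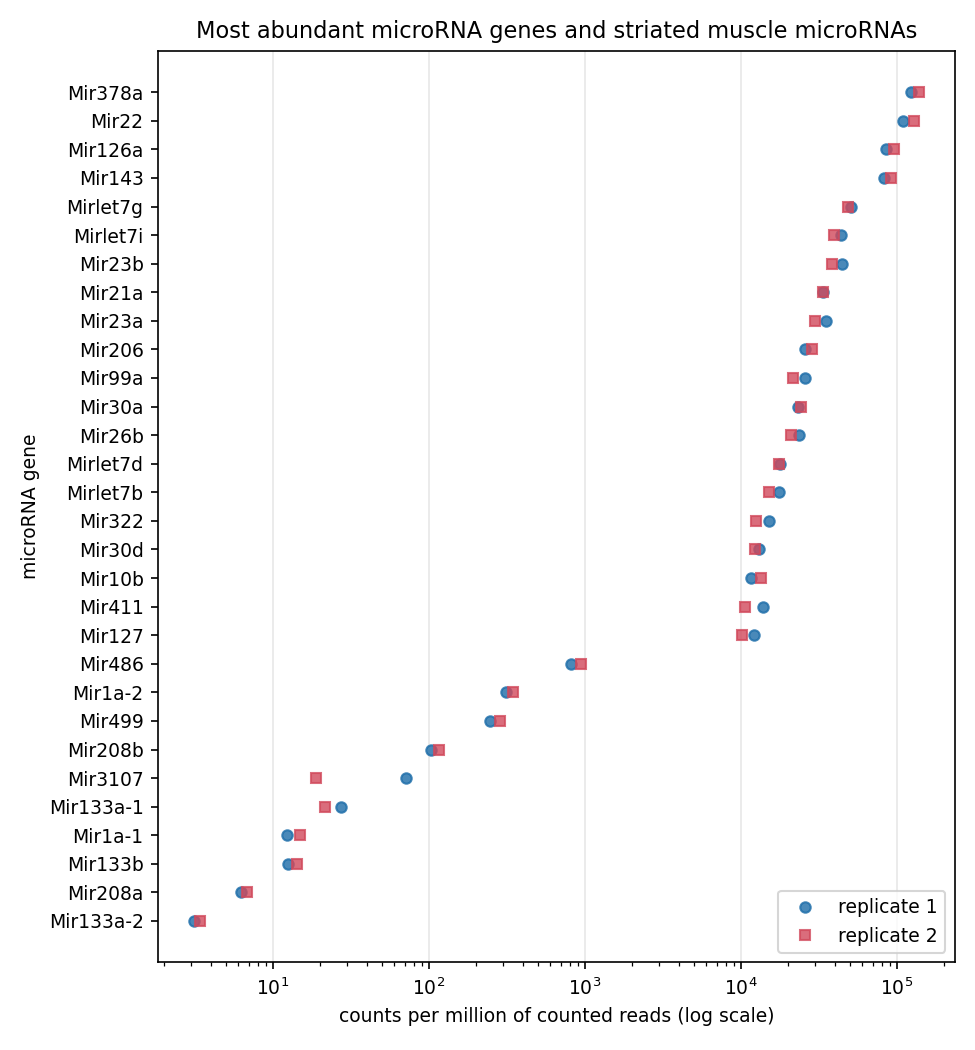
Abundance of the 20 leading microRNA genes and of the striated muscle microRNAs, as CPM of counted reads on a log axis, with circles for replicate 1 and squares for replicate 2. Mir378a and Mir22 stand highest, at means of 130385 and 119561 CPM, and Mir206 lies far above the other striated muscle genes, of which Mir486 is next at 881 CPM.

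The microRNAs best known from striated muscle were compared next. In reads counted in single genes, Mir206 dominated them, with 106820 counts in replicate 1 and 92373 in replicate 2. Mir486, which lies in an intron of Ank1 and is shared by muscle and red cells, had 881 ± 96.3 CPM. Mir1a-2 had 331 ± 22.8 CPM, and the myosin-intron microRNAs Mir499 and Mir208b had 266 ± 27.4 and 109 ± 8.85 CPM. The 11 genes of this list together held 2.90% ± 0.214 of counted reads.

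Mir206 (ENSMUSG00000065559.1) lies on the plus strand of chromosome 1 from 20679010 to 20679082, in an exon of the noncoding RNA Gm28653. Mir133b lies in an exon of the same noncoding RNA from 20682769 to 20682887. Despite this shared host, Mir206 was counted 2010.5-fold above Mir133b, a log2 ratio of Mir133b over Mir206 of −10.97 ± 0.02. Mir133b had 13.4 ± 1.21 CPM, Mir133a-1 had 24.5 ± 3.95 CPM and Mir133a-2 had 3.28 ± 0.193 CPM. Mir1a-1 had 13.6 ± 1.82 CPM, and Mir1a-2 exceeded it 24.1-fold.

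The counts of the Mir1a and Mir133a loci are uncertain, since reads aligned to several loci are taken to be in no gene's count. These loci and Mir133b each share a stretch of at least 20 bases with another annotated hairpin, whereas Mir206, Mir208a, Mir208b and Mir499 share none. Sharing between hairpins that overlap on opposite strands, such as Mir486 and Mir3107, was not examined, so their counts can carry the same uncertainty.

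The microRNAs in introns of myosin heavy chain genes were far less abundant than Mir206. Mir499, in Myh7b, exceeded Mir208b, in the slow myosin gene Myh7, 2.43-fold (log2 ratio 1.28 ± 0.03, n = 2). Mir208a, in the cardiac myosin gene Myh6, had 26 counts in replicate 1 and 22 in replicate 2, or 6.56 ± 0.385 CPM. Mir206 exceeded Mir208b 249-fold (log2 ratio 7.96 ± 0.01). The 3 myosin-intron genes together held 0.0382% ± 0.00367 of counted reads.

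The denervation and regeneration list, made of Mir206, Mir21a and Mir31, held 6.09% ± 0.222, nearly all of it from Mir206 and Mir21a. Mir31 had 45.4 ± 26.8 CPM, from 266 counts in replicate 1 and 85 in replicate 2. The metabolic muscle list held 28.3% ± 1.99, mostly as Mir378a, Mir22 and Mir23a, while its member Mir494 had 184 ± 54.1 CPM.

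Among microRNA families, let-7, known for its rise with differentiation, held the largest share at 13.6% ± 0.676, with all 12 members at 10 or more counts in both libraries. Mirlet7g, Mirlet7i, Mirlet7d and Mirlet7b led it. None of these shares a stretch of 20 bases with another hairpin, while every let-7 locus with a copy number in its symbol does. The order and the family shares here therefore cover reads aligned to 1 locus. They can undercount families with copies, such as miR-26 and miR-29. The miR-23, miR-27 and miR-24 clusters held 8.63% ± 0.870, and the miR-10 and miR-100 family, encoded partly within Hox gene clusters, held 5.56% ± 0.295. The miR-30 family held 4.52% ± 0.0521, the miR-26 family 2.28% ± 0.195 and the miR-29 family 0.384% ± 0.00457. The 42 listed microRNAs of the imprinted Dlk1-Dio3 region held 4.74% ± 0.812, with Mir411, Mir127, Mir379 and Mir299a the most abundant. Mir494, Mir770, Mir341 and Mir1193 lie in that region but outside the list. Mir335, in an intron of the imprinted gene Mest, reached 7764 ± 1300.4 CPM and made up most of the 0.839% ± 0.136 of the other imprinted microRNAs.

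The proliferation-associated cluster within Mir17hg, led by Mir17 at 1394 ± 153 CPM, held 0.292% ± 0.0215, and its relative miR-106b-25, within Mcm7, held 0.235% ± 0.0228. The third cluster of this group, miR-106a-363 on the X chromosome, held 0.00545% ± 0.00314, or 0.00767% in replicate 1 and 0.00323% in replicate 2. Its members Mir20b, Mir106a and Mir363 had 15.3 ± 11.9, 13.3 ± 10.5 and 11.2 ± 9.19 CPM, each higher in replicate 1, and Mir92-2 had 14.4 ± 0.232 CPM.

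Genes of 1 cluster or family differed by far more than the replicate SD. Mir27b was below its neighbour Mir23b by 4.22-fold (log2 ratio of Mir27b over Mir23b −2.08 ± 0.03) and above its neighbour Mir24-1 by 121-fold (log2 ratio 6.92 ± 0.12). Mir143 exceeded Mir145a, its neighbour on chromosome 18, 34.8-fold (log2 ratio 5.12 ± 0.02). Within Mcm7, Mir93 exceeded Mir25 6.10-fold (log2 ratio 2.61 ± 0.15). Mir30a exceeded Mir30d 1.87-fold, and Mir29a exceeded Mir29c 2.04-fold (log2 ratio 1.03 ± 0.13). The duplicated loci Mir26a-1 and Mir26a-2 differed 47.5-fold, with 11.7 ± 1.09 and 564 ± 105 CPM, and Mir133a-1 exceeded Mir133a-2 7.18-fold (log2 ratio 2.84 ± 0.32).

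All 14 fixed pairs kept their direction in both libraries, but an exact two-sided sign-flip test over 2 libraries cannot give a p below 0.5. Mir23b, Mir27b, Mir24-1, Mir29c, Mir26a-1 and Mir26a-2 also share a stretch of 20 bases or more with another hairpin, so the ratios that hold them carry the same uncertainty as those of Mir1a and Mir133a. In the column that ignores strand, where reads of genes with an opposite-strand microRNA are ambiguous, the log2 ratios reversed to −19.73 for Mir378a over Mir22, 6.64 for Mir1a-1 over Mir1a-2 and −9.34 for Mir451a over Mir144.

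Markers of other cells in the muscle were then summed by list. Endothelium, represented by Mir126a, held 9.06% ± 0.737 of counted reads. Smooth muscle and fibroblasts held 9.07% ± 0.560, of which Mir143 made up nearly all. Mir199a in this list is encoded at more than 1 locus, so its reads can be undercounted. Mir145a had 2501 ± 137 CPM, Mir214 had 1095 ± 270.0 CPM and Mir199b had 74.0 ± 22.9 CPM. Leukocytes held 0.238% ± 0.00696, led by Mir155 at 791 ± 113 CPM, followed by Mir150 at 509.9 ± 28.2 CPM, Mir146 at 500.2 ± 32.6 CPM and Mir223 at 368 ± 96.0 CPM.

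Red cell microRNAs held 0.0399% ± 0.000802, with Mir451a 3.51-fold above its neighbour Mir144 (log2 ratio 1.81 ± 0.12). The neuron and glia list held 0.430% in replicate 1 (exact Clopper-Pearson 95% interval 0.423 to 0.436) and 0.124% in replicate 2 (0.121 to 0.128). Mir338, in an intron of Aatk, accounted for nearly all of it, with 17718 counts in replicate 1 and 3980 in replicate 2. Mir219a-2 had 38 and 15 counts, Mir219a-1 had 13 and 11, and the other 6 members, 3 loci of Mir124a and 3 of Mir9, had 0 in both libraries. All 6 share at least 20 bases with another hairpin, so their counts of 0 do not show absence.

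Epithelium and skin held 0.0227% ± 0.00153, mainly as Mir203 at 214 ± 8.57 CPM, while Mir200c, Mir200b and Mir205 had 27, 13 and 15 counts in replicate 1 and 11, 6 and 4 in replicate 2. The endocrine list held 0.00486% ± 0.000509, mainly as Mir7-1 at 44.0 ± 3.41 CPM, with Mir375 at 1.62 ± 0.0990 CPM from 7 and 5 counts. Mir7-1 lies in an intron of Hnrnpk, and whether its reads came from endocrine cells was not tested. It carries a copy number in its symbol, so its count can miss reads aligned to several loci. The liver microRNA Mir122 held 0.00126% ± 0.00112, from 85 counts in replicate 1 and 15 in replicate 2.

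**Figure D2:**
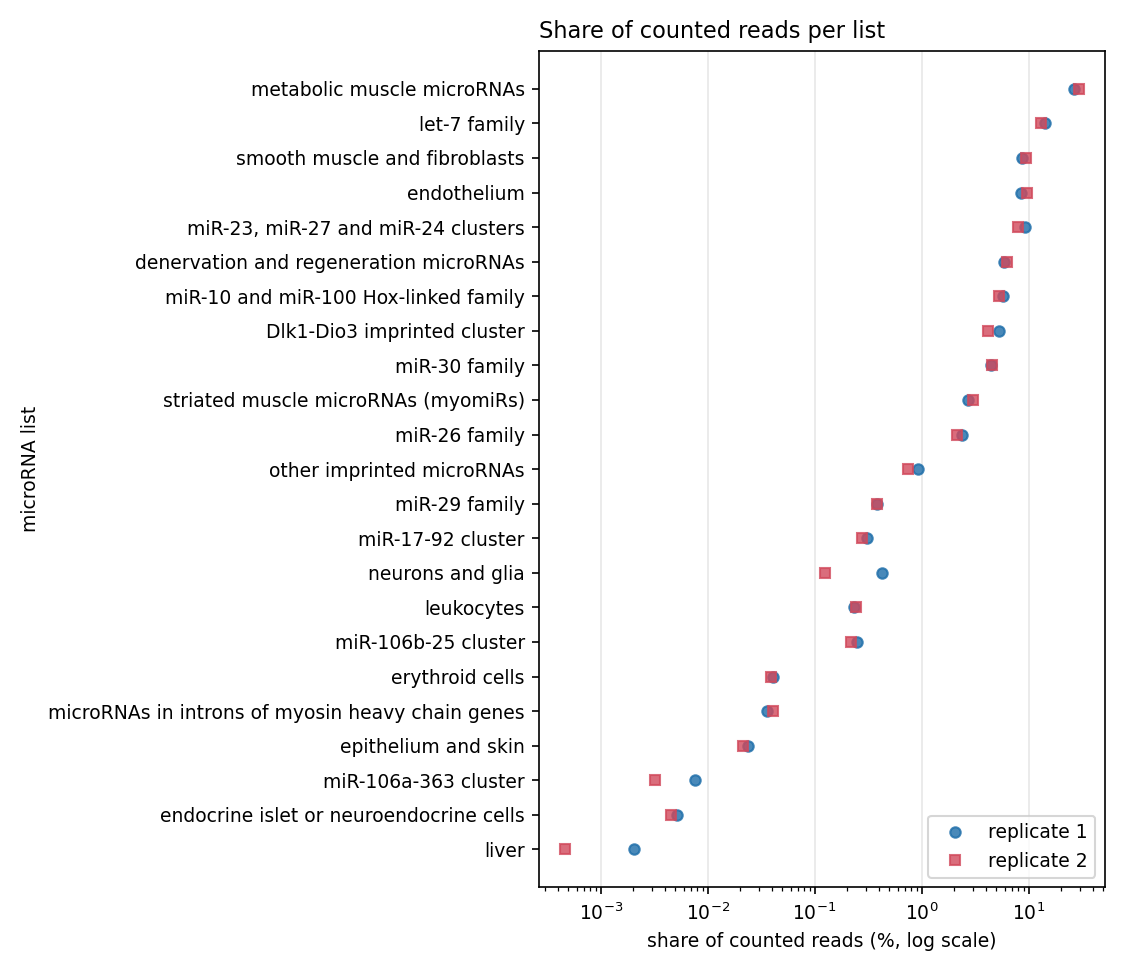
Share of counted reads held by each microRNA list, in percent on a log axis, with circles for replicate 1 and squares for replicate 2. The metabolic muscle list stands highest at a mean of 28.3%, and the neuron and glia list differs visibly between the libraries, at 0.430% and 0.124%.

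The other comparison was between the 2 animals. The 4 leading genes were higher in replicate 2, with log2 ratios of replicate 2 over replicate 1 of 0.32 for Mir378a, 0.40 for Mir22, 0.33 for Mir126a and 0.30 for Mir143. Of the leading 20 genes, 12 were higher in replicate 2, or 8 under total-count scaling and 15 under DESeq2 size factors, and their ratios ran from −0.21 for Mir411 to 0.40 for Mir22. Of 261 genes with a mean of at least 10 CPM, 155 (59.4%) differed by less than 1.2-fold, a tolerance chosen after the data were seen. These ratios follow TMM scaling, which trims the most extreme genes. The median absolute log2 ratio was 0.18. Over 2-fold, 13 genes were lower in replicate 2 and 1, Mir1199, was higher.

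Mir183 and Mir182, neighbours on the minus strand of chromosome 6 known from sensory neurons and hair cells, differed most. Mir183 (30169668 to 30169737) had 412 counts in replicate 1 and 31 in replicate 2, 8.48-fold lower in replicate 2 (log2 ratio −3.08). Mir182 (30165918 to 30165992) had 399 and 41 counts, 6.35-fold lower (log2 ratio −2.67). Mir338 (ENSMUSG00000065600.1, chromosome 11, 120014765 to 120014862, minus strand) was 3.09-fold lower (log2 ratio −1.63) and was the most abundant gene past 2-fold. Between Mir182 and Mir338 in size of fall came Mir122 (log2 ratio −1.78), Mir3107 (−1.70) and the neuronal Mir137 (−1.67). Mir3107, also called Mir486b, lies opposite Mir486, and it had 295 and 61 counts where Mir486 had 3363 and 3057.

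The X-linked Mir363, Mir106a and Mir20b were also lower in replicate 2, with log2 ratios of −1.57, −1.51 and −1.50, as was Mir31 at −1.09. The 3 other genes past 2-fold, named after their values were seen, were Mir138-2 (−1.44), Mir138-1 (−1.27) and Mir184 (−1.02). Mir1199 had 29 and 45 counts (log2 ratio 1.05), and the next highest ratios belonged to Mir378d (0.80), Mir181a-2 (0.77), Mir185 (0.63) and Mir874 (0.60).

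**Figure D3:**
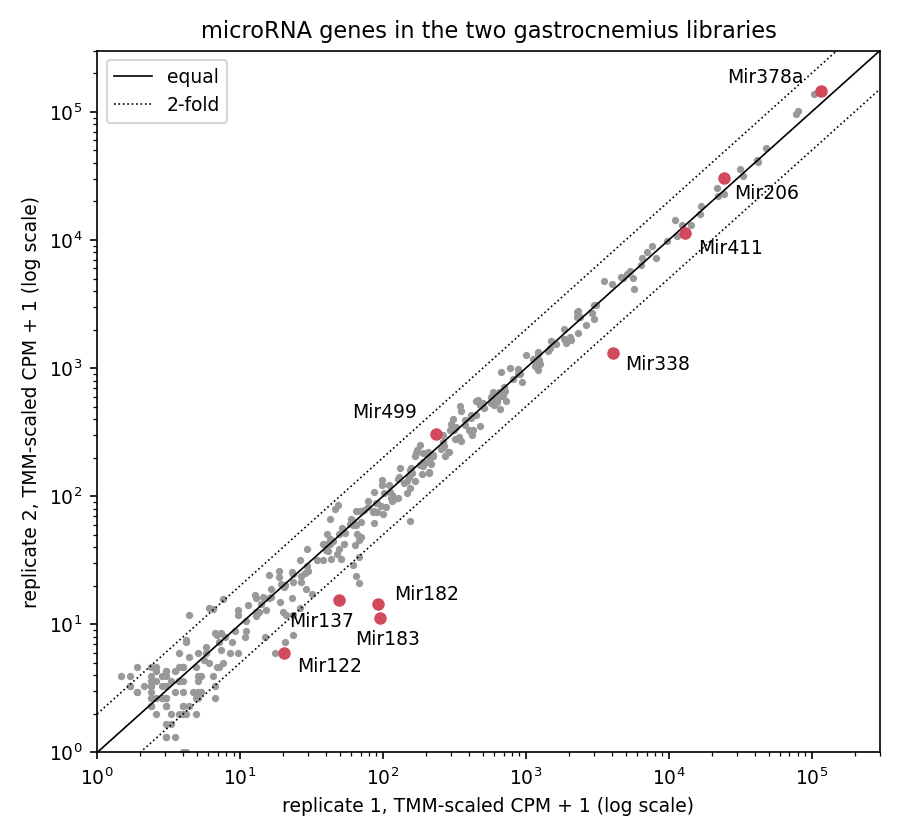
Each point is 1 microRNA gene with at least 10 counts summed over both libraries, plotted by TMM-scaled CPM + 1 in replicate 1 and replicate 2 on log axes, with lines of equality and of 2-fold difference. Mir378a and Mir206 lie within the 2-fold lines, and Mir338, Mir183, Mir182, Mir137 and Mir122 lie below them, with log2 ratios from −1.63 for Mir338 to −3.08 for Mir183.

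A chi-square of 111.5 per degree of freedom over 362 genes set the libraries apart as reads, which serves as a check that they are not 1 library entered in duplicate. Separate animals are bound to exceed counting noise at this depth, so it says no more than that. The biological coefficient of variation estimated by edgeR was 21.4%. Across genes, which are not independent replicates, log2(CPM + 1) had a Pearson r of 0.989 and a Spearman rho of 0.983. The single-gene ratios rest on 1 library per side and have no replicate check, and with a minimum of 100 CPM in place of 10 the count past 2-fold was 2, both lower in replicate 2.

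Several lists stood apart in these 2 libraries, a description without replicates. The random lists draw genes independently, while several lists hold neighbours that are not independent, so their percentiles can be too extreme. Such neighbours include Mir30b with Mir30d, Mir30c-1 with Mir30e, Mir206 with Mir133b, Mir133a-1 with Mir1a-2, Mir143 with Mir145a, Mir214 with Mir199a-2, and Mir486 opposite Mir3107. Of the 41 Dlk1-Dio3 microRNAs tested, 38 were lower in replicate 2, with a median log2 ratio of −0.22, below all of 10000 random lists matched on expression, though these members share 1 locus. Mir411 (−0.21), Mir127 (−0.09), Mir379 (−0.15) and Mir299a (−0.28) were among them. The miR-106a-363 cluster had a median of −1.51 (percentile 0.05), with 3 of 4 members lower and Mir92-2 at 0.19, and its members also share 1 locus. Mir92-2 carries a copy number in its symbol, so its count can miss reads aligned to several loci.

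Striated muscle microRNAs lay higher in replicate 2 for 7 of 9 members, with a median of 0.33 (percentile 99.95). Mir1a-1 (0.41), Mir486 (0.39), Mir499 (0.38) and Mir206 (0.32) were among the 7, and Mir133a-1 (−0.16) and Mir3107 (−1.70) were the others. All 6 miR-30 members were higher (median 0.23, percentile 98.5), or 5 of 6 under scaling to the total count. The miR-10 and miR-100 family had a median of 0.18 (percentile 98.4) with 6 of 8 higher, or 5 of 8 under total-count scaling. Leukocyte microRNAs had a median of 0.28 (percentile 98.1) with 4 of 5 higher, or 3 of 5 under total-count scaling.

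Smooth muscle and fibroblast genes split. Mir143 and Mir145a were higher in replicate 2, at 0.30 and 0.28, while Mir214 (−0.34) and Mir199b (−0.47) were lower. Their median of −0.32 (percentile 0.09, with 4 of the 5 tested members in 2 pairs of neighbours) turned to 0.28 when members below 100 CPM were left out.

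The median of let-7 was −0.02 (percentile 44.1), with 6 of 12 members higher, but all 12 were lower under total-count scaling. The other lists tested had medians of 0.18 for denervation and regeneration (percentile 83.2), 0.13 for metabolic muscle (74.9), 0.01 for miR-29 (70.7), 0.01 for the Mir17hg cluster (61.6), and 0.00 for miR-26 (53.0). They were −0.05 for the other imprinted genes (39.9), −0.07 for miR-106b-25 (42.3) and −0.02 for the miR-23, miR-27 and miR-24 clusters (35.03). Of these 8 medians, those for metabolic muscle, miR-29 and the Mir17hg cluster were below 0 under total-count scaling, while those for miR-26, the other imprinted genes and the miR-23, miR-27 and miR-24 clusters were above 0 under DESeq2 size factors. The median over all 261 genes was −0.05 under TMM, −0.21 under total-count scaling and 0.00 under DESeq2, and a list's direction depends on it. Relative to that median, which cancels the scaling factor by construction, the Dlk1-Dio3 list stood at −0.17 and striated muscle microRNAs at 0.38 under TMM.

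**Figure D4:**
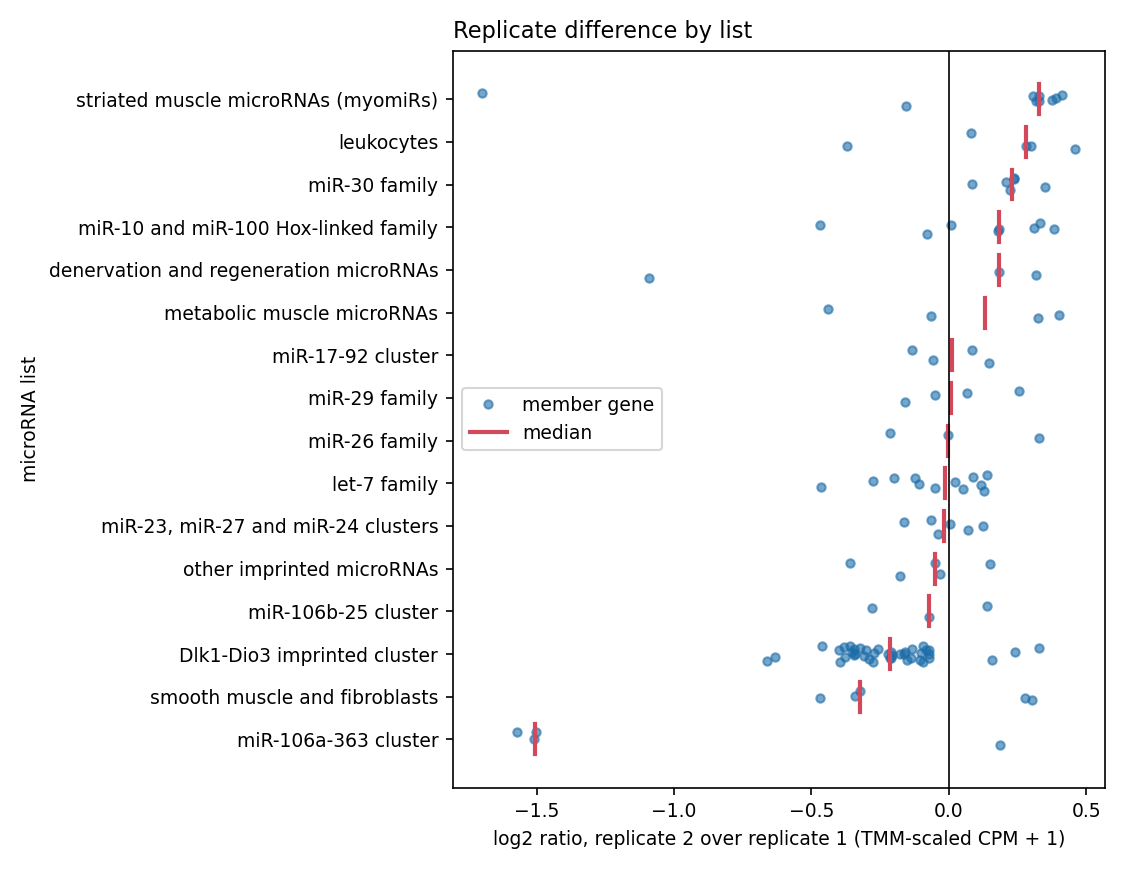
Log2 ratio of replicate 2 over replicate 1 for every list with at least 3 genes above 10 CPM, where each point is 1 member gene and the red bar is the list's median. The Dlk1-Dio3 genes lie mostly left of 0 (median −0.22), the miR-106a-363 genes furthest left (median −1.51) and the striated muscle genes mostly right of 0 (median 0.33), under TMM scaling.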

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

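The alternative scalings and the placing of the Dlk1-Dio3 median among matched lists were planned, while the other tests in this part, and the bounds by which all were judged, were chosen after the results were seen. The reads flagged first lie in data that the comparisons did not use and exceed what a count of 0 allows. Reads aligned to several loci numbered 13878974 in replicate 1 and 12282813 in replicate 2. Reads aligned outside annotated microRNA genes numbered 320898 and 252855. Reads on the strand opposite to a gene, where no microRNA is annotated, numbered 43 and 25.

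The Mir1a and Mir133a loci, encoding microRNAs known as abundant in muscle, had few counts, from 13 for Mir133a-2 to 1301 for Mir1a-2 in replicate 1. Reads shared between copies are a candidate explanation: within the fixed families, the 16 members whose symbol carries a copy number differed from the 24 others by −5.40 log2 units (permutation p = 0.0001, the smallest that 10000 permutations can give). All 4 of these loci share at least 20 bases with another hairpin, although Mir23a and Mir23b do too and were abundant. Low abundance in the tissue stays open, because the reads aligned to several loci (71.8% of all reads on average) are not divided by gene. The reads in that row from Mir1a or Mir133a were not measured here.

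Mir338, Mir183 and Mir182 were lower in replicate 2, with 17718 against 3980 counts for Mir338. Counting noise is argued against, since the highest upper 95% counting limit of the 3 ratios was 0.335. The highest log2 ratio over 3 scalings was −1.57, but these scalings moved the median of all genes only between −0.21 and 0.00. Scalings this close could not have brought the 3 ratios near 0, so that check was settled in advance. More nerve tissue in replicate 1 stays open: of 13 other nerve-expressed microRNAs, 4 passed the minimum, with a median log2 ratio of 0.0667 (percentile 82.3 of matched lists), and muscle also expresses 2 of those. The other 2 had a median of −0.0059 (SE 0.176 over members), too few and too spread to decide. The most abundant of the 13, Mir128-1, which muscle also expresses, had 3542 and 2492 counts (0.02). Scarce members went both ways, such as Mir383 with 25 and 5 counts and Mir218-2 with 6 and 11. Mir96, also among the 13 but below the minimum, is the third member of the Mir183 cluster and so no separate evidence. It had 18 and 5 counts, with 95% counting limits of the ratio from 0.116 to 1.12. Outside the 13, the neuronal Mir137 was also lower in replicate 2 (−1.67), though it was named for its fall. The labels name no difference between the animals that could be set against these.

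The Dlk1-Dio3 microRNAs were lower in replicate 2 for 38 of 41 members, which share a locus, so errors over members are too small for the cluster as 1 unit. Hairpin GC content is argued against as the whole cause, as a linear trend would need a slope of 0.05 log2 units per percent GC, and the slope over the other 220 genes was 0.00389 with an upper 95% limit of 0.0122 when genomic clusters were resampled. A common scaling factor is argued against too, since it cancels in the difference from the other genes, which was −0.22 (SE 0.03 over members). Those other genes include Mir494, Mir770, Mir341 and Mir1193, which lie in the same locus but outside the list. Ordinary spread between loci stays open: 12 of 34 other genomic clusters had a mean at least as far from the median of all genes, among them 3 of the 5 with 4 or more genes, and the percentile of 0 among 10000 matched lists does not decide this, because those lists draw genes independently. The labels name no difference between the animals, and no biological explanation was tested for this pattern.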

How the results depend on the processing

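All alternatives were fixed before the data were examined. Of 559 alternative values over 90 results, 401 stayed within their bound, 154 moved further and 4 reversed. The bound was the replicate SD for abundances, shares and pairs, and 1.5 times for counts and the coefficient of variation. List medians had the SE over members, single-gene ratios the counting error, and the chi-square its test outcome. The 401 include 59 values for each replicate left out. Leaving out a replicate moves a mean of 2 by less than their SD by construction, so it says nothing about stability. Replicate differences have no value with 1 library. All 44 TMM values are also included, though the 2 factors nearly cancel in a mean. The 401 is therefore no measure of stability. No paired analysis was possible because there is 1 group. In the column that ignores strand, reads of genes with an opposite-strand microRNA are ambiguous, which reversed 3 pair ratios: Mir1a-1 over Mir1a-2 (6.64), Mir451a over Mir144 (−9.34) and Mir378a over Mir22 (−19.73). It moved Mir27b over Mir24-1 to 16.12. Genes of the other 10 of 14 pairs have no opposite-strand microRNA and the same counts in both columns, so their unchanged ratios are no check. The column gave shares of 3.69% for striated muscle, 17.8% for let-7, 5.67% for Dlk1-Dio3, 8.45e-05% for endothelium, 12.1% for smooth muscle and 0% for neurons and glia. Without Mir378a the shares were 3.33% for striated muscle, 15.7% for let-7, and 10.4% each for endothelium and smooth muscle. Per all reads, the leading 10 genes held 13.1%, striated muscle 0.580%, let-7 2.74%, Dlk1-Dio3 0.958%, endothelium 1.82%, smooth muscle 1.82%, and neurons and glia 0.0570%. With no minimum, 41 genes passed 2-fold (29 lower in replicate 2, 12 higher), and at 100 CPM 2 did (2 lower, 0 higher). The count of higher genes was 3 ignoring strand, 0 under total-count scaling and 0 with a pseudocount of 5 CPM. Total-count scaling moved the let-7 median to −0.18 and that of Dlk1-Dio3 to −0.38, and DESeq2 factors moved the latter to −0.16. The smooth muscle median reversed to 0.28 at 100 CPM, where fewer genes remain. Detected genes numbered 474 at 1 count and 292 after thinning replicate 1 to 3219740 reads, so the minimum limits detection more than the depth gap does.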

Other observations

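The 2 tests at the end of this part were planned before their results were seen, while the genes in the first paragraph and the test of abundance within clusters were chosen after the values were seen. Several abundant microRNAs stand in none of the lists. Mir139 had 6822 ± 34.4 CPM (SD, n = 2), Mir195a 6374 ± 566 CPM and Mir191 5558 ± 188 CPM. Mir151 had 5271 ± 178 CPM, and Mir140, known from cartilage, had 4879 ± 46.2 CPM. Mir149 had 4096 ± 539 CPM and was higher in replicate 2, with a log2 ratio of 0.44, and Mir130a had 2743 ± 637 CPM with a ratio of −0.31.

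Neighbouring hairpins were counted at very different levels. On the X chromosome, 6 genes from Mir450b to Mir322 (53047997 to 53054349) spanned 10.34 log2 units. The 32 genes from Mir379 to Mir410 on chromosome 12 (109709060 to 109743795) spanned 9.33 log2 units. Mir182 and Mir183, by contrast, both averaged 54.6 CPM (SD 59.2 and 63.6, n = 2). Over 37 clusters of hairpins within 10000 bp, the SD of abundance within a cluster was 2.66 log2 units against 2.96 when values were permuted among the 131 genes (permutation p = 0.0080).

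A hypothesis was that neighbouring hairpins differ between the animals together, as joint transcription would give. The SD of log2 ratios within clusters was 0.25 against 0.47 under permutation (permutation p = 0.0001, the smallest that 10000 permutations can give), which is consistent with it. Mir206 and Mir133b, for example, had ratios of 0.32 and 0.33, and Mir143 and Mir145a had 0.30 and 0.28. The Dlk1-Dio3 genes alone did not account for this. With all hairpins of that locus left out, the 34 other clusters, with 86 genes, gave 0.29 against 0.56 (permutation p = 0.0001). The clusters furthest from 0, Mir182 with Mir183 (mean −2.88) and miR-106a-363 (mean −1.10), stayed in both tests. They were not left out in turn, so how far the result rests on them was not tested. Exceptions remained, such as Mir92-2 (0.19) beside Mir363 (−1.57), and Mir181a-2 stood at 0.77 where its cluster of 2 genes had an SD of 0.48. Both Mir92-2 and Mir181a-2 carry a copy number in their symbol, so their counts can miss reads aligned to several loci. Whether these exceptions reflect separate behaviour of the loci was not tested.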
